A study of Homo sapiens with 4 samples.

How the data were processed

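Total RNA was taken from 4 samples of a human pulmonary epithelial cell line, titled Calu by the submitters, that had been transduced with lentivirus. Lentivirus inserts its cargo into the genome of the cells. In 2 samples the virus carried the human microRNA miR-223 and in 2 it was a control virus. The RNA was labelled with biotin and hybridised to the Affymetrix Human Gene 1.0 ST array, which measures transcripts with sets of short probes, per the series text. Each sample is a separate array. Nothing in the labels says whether the samples of a group came from separate transductions or cultures, so the p-values measure only the spread between these samples, which may be technical.

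The authors deposited 1 table of log2 expression values with 33297 probe sets and 4 columns. RMA (robust multi-array average, which corrects background, normalizes arrays to each other and summarises probes) and Partek are named in the submitters' processing notes, and Partek Genomics Suite 6.6 was used for quality control per the series text. The settings are not given in the sources used here. That the values are on the log2 scale was read from the deposited values, which ran from 1.23 to 13.2. The array scanner files were not used here. RMA draws arrays to a common distribution, so a change shared by most genes would not show, and it compresses fold changes of dim probe sets. No detection call came with the values. There were 6 dim genes with identical values on all 4 arrays.

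Probe sets were named through GEO's platform annotation, which listed 21214 of them. Of these, 19460 were paired with exactly 1 gene symbol and 1754 with several. The remaining 12083, control probe sets among them, are unnamed here. For the 769 genes with more than 1 single-gene probe set, the probe set with the highest mean over the 4 arrays was used, which left 18417 genes. The Entrez identifiers of 18388 of these were found in the RefSeq gene table of GRCh38.p14, with 0 differences in symbol. The build behind the array design is not given in the sources used here, so no coordinates are printed.

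Differences (miR-223 minus control) were tested per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or block, two-sided), and p-values were adjusted by Benjamini-Hochberg over the 18417 genes with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene, and moderation added 3.94. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so no such test is reported for single genes. The number of arrays limits the precision. On simulated values with the spread of these arrays, the same test recovered 64% of genes changed 2-fold and 96% of those changed 4-fold. It recovered 4% of those changed 1.5-fold and called 12 unchanged genes. The simulation held 200 changed genes, and the adjusted threshold is easier to pass when many genes change. Where few genes change, as few were called here, recovery would be lower than these shares.

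Before the data were examined, 22 gene lists with 593 symbols were written from general knowledge, of which 548 had a tested probe set. They cover miR-223 targets from the literature, the PARP family, inflammasome genes, epithelial junctions and keratins, airway secretory genes, mesenchymal genes, inflammatory genes, interferon-stimulated genes, mitotic and DNA replication genes, cholesterol synthesis, unfolded protein and amino acid stress, hypoxia and glycolysis, p53 targets, insulin-like growth factor and FOXO signalling, microRNA machinery, ribosomal proteins, and markers of myeloid cells, lymphocytes, endothelium, alveolar epithelium and ciliated cells. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run beside it, and so was fry, which tests whether a list moves one way on balance and does not compare it with other genes. With an estimated correlation camera uses only the 2 residual degrees of freedom, so it can hardly pass any list. A call lost there does not show that a list was unshifted. On simulated values camera at the preset correlation called 0 lists when none was shifted and called a list shifted by -0.2. That shift exceeded in size every list median in the data (at most 0.16), so recovery of smaller shifts was not shown. The simulated genes varied independently of each other. The simulation therefore could not show how often a list is called only because its members move together.

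The genes named in the text follow a rule also set before the data were examined. It takes up to 10 rises and 10 falls among genes with non-overlapping groups and a mean of at least 6 in the higher group, those past the threshold first and then by unadjusted p, together with MIR223, PARP1 and up to 4 members of each list by p. Of the 86 such members, 12 lay below the lower quartile of the tested genes on both arrays of at least 1 group, 10 of them on all 4 arrays, and no values are given for these 12. Alternatives were the replicate number as a block, an intensity trend, robust or no variance moderation, filters on dim genes, quantile normalization or median centring, all probe sets, the mean of a gene's probe sets, a threshold of 0.10, array weights, and leaving out each array in turn. A planned comparison of genes by miR-223 sites in their 3′ UTR was not run, since UTR sequences were not used here. Figures were drawn with matplotlib 3.10.9.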

Results

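Gene expression was profiled in a human pulmonary epithelial cell line carrying either a miR-223 lentivirus (n = 2 arrays) or a control lentivirus (n = 2 arrays). The series text states that such cells have hardly any miR-223 of their own and gain it from neutrophils in co-culture. The comparison asked which transcripts differ once the microRNA is supplied by the virus. The median expression of the 18417 tested genes lay between 5.06 and 5.11 on the log2 scale on the 4 arrays. Pearson's r across genes was 0.993 between the 2 miR-223 arrays and 0.993 between the 2 control arrays, and between 0.991 and 0.995 for arrays of different groups. Genes are not independent replicates, so these correlations only describe the arrays.

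The microRNA gene itself was measured first. MIR223 (probe set 8167971, which matches the precursor) rose from 3.30 ± 0.14 in control cells to 8.70 ± 0.50 in miR-223 cells (log2, mean ± SD, n = 2 each), a measured log2 difference of 5.41. The second gene that rose was RTL1 (probe set 7981322), an imprinted gene derived from a retrotransposon, from 3.33 ± 0.08 to 6.57 ± 0.14, a measured log2 difference of 3.24. In control cells both probe sets lay below the lower quartile of the tested genes (3.51 and 3.56 on the 2 control arrays) and are not shown to be above background, so no exact fold is given. The limma adjusted p was 0.0048 for MIR223 and 0.0042 for RTL1. These 2 were the only genes past the threshold among 18417 in this fit, and 0 genes fell. At an unadjusted p under 0.05 there were 888 genes, 488 higher and 400 lower, where 921 would be expected with no effect. The fit had no block, so spread between replicate numbers can lower this count, which does not show an absence of effect. Both calls were lost when all 33297 probe sets were tested (limma adjusted p = 0.107 for MIR223 and 0.082 for RTL1) and when variances were not moderated (0.793 and 0.789). Without control replicate 2 the adjusted p was 0.052 for each, and RTL1 also missed the threshold without miR-223 replicate 1 (0.121) or 2 (0.093).

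**Figure D1:**
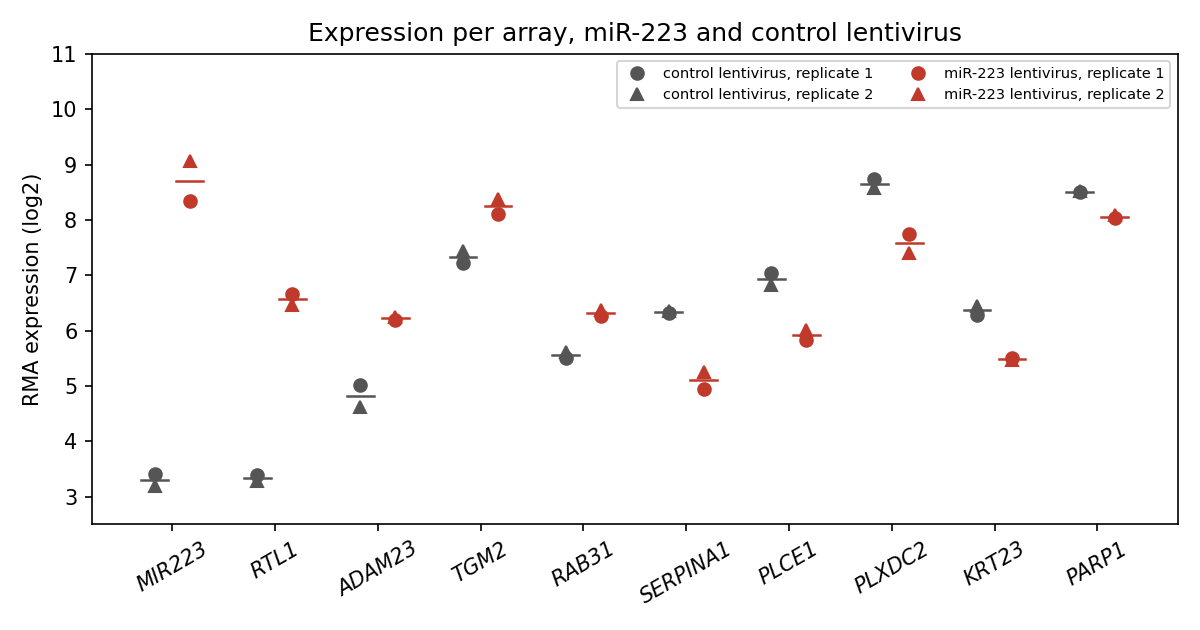
Expression of 10 genes on each of the 4 arrays (y axis, RMA value on the log2 scale; x axis, gene; circles replicate 1, triangles replicate 2, lines group means). MIR223 and RTL1 stand apart between the groups, with control values not shown to be above background, while PARP1 differs by -0.45.

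Beyond these, the leading genes did not pass the adjusted threshold. The smallest limma adjusted p of any other gene was 0.275, and those named here were taken by unadjusted p among genes with a mean of at least 6 in the higher group, so larger differences exist elsewhere. Among genes with higher values in miR-223 cells, ADAM23, a membrane protein of the disintegrin family, was at 2.64-fold (log2 difference 1.40 ± 0.16 SE). TGM2, a transglutaminase that cross-links proteins, was at 1.88-fold and RAB31, a small GTPase of vesicle transport, at 1.70-fold. PLLP (1.70-fold), the myosin MYO1D (1.56-fold), the small heat shock protein HSPB1 (1.44-fold), NNMT (log2 difference 0.59) and AVPI1 (1.41-fold) completed the leading genes on this side. Among genes with lower values, AGMO, a lipid monooxygenase, was at -1.40 ± 0.24 (log2 difference ± SE) and SERPINA1, which encodes alpha-1 antitrypsin, at -1.24 ± 0.13. PLXDC2 was at -1.08, SLC41A2, a magnesium transporter, at -1.07, PLCE1, a phospholipase C, at -1.02, and the keratin KRT23 at -0.88. The glucose transporter SLC2A2 was at -0.79, HEXIM1, an inhibitor of the elongation factor P-TEFb, at -0.60, RERG at -0.60 and GATM, the first enzyme of creatine synthesis, at -0.56. In all 18 genes both miR-223 arrays lay on the same side of both control arrays, which the rule for naming them required. Over all genes 31.9% had such non-overlapping groups, where chance gives 33.3%. A difference of at least 1.5-fold, at any p, was seen in 123 genes, 65 higher and 58 lower, and a 2-fold difference in 23.

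MiR-223 lowers the transcripts it binds, and the literature names many targets. PARP1 (probe set 7924733), a poly(ADP-ribose) polymerase of the DNA damage response that the study is known to have followed as a target, averaged 8.06 ± 0.04 in miR-223 cells and 8.51 ± 0.02 in control cells (log2, mean ± SD, n = 2 each). The difference was -0.45 (95% interval -0.71 to -0.20), which is 0.73 of the control level. Its unadjusted limma p was 0.0052 and its adjusted p 1 over all genes and 0.192 adjusted over the list alone, so it did not pass. By unadjusted p, 79 genes ranked before it, of which 38 were lower in miR-223 cells. The series text says that these arrays served to find targets, so a target chosen from them is not independent evidence of its direction. Of 37 measured literature targets, 21 were lower and 16 higher, 0 passed either over all genes or adjusted over the list alone, and the list median was -0.03 (camera adjusted p = 0.655, downward; upward without control replicate 1, 0.989). RCN2, a calcium-binding protein, was at -0.22, whereas the FOXO3 transcription factor was at 0.34 and SCARB1, a lipoprotein receptor, at 0.25. In the PARP family list of 23 genes, 12 were lower and 11 higher (median -0.03, camera adjusted p = 0.272), with MACROD1, an ADP-ribose hydrolase, at 0.36, OARD1 at -0.34 and PARP14 at -0.23. The inflammasome list was also near 0 (17 genes, median -0.02, camera adjusted p = 0.655). NEK7 was at 0.26, NAIP at -0.33 and PYCARD at 0.23.

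Genes of protein and amino acid stress and of hypoxia were higher as lists in miR-223 cells, and genes of DNA replication and mitosis were lower as lists, by camera with a preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.878 for each). With 2 arrays per group that form of camera has little power, so the loss does not show that the lists were unshifted. The myeloid marker list, described last, was higher beside them (median 0.09; adjusted p = 0.878 with an estimated correlation). Single members did not pass, with 0 called in any of these 4 lists over all genes or adjusted over the list alone. In the stress list 19 of 26 genes were higher (median log2 difference 0.10, camera adjusted p = 0.030), led by DDIT4, an mTOR inhibitor, at 0.47, the cystine transporter SLC7A11 at 0.69, SDF2L1 at 0.33 and TRIB3 at 0.40. In the hypoxia and glycolysis list 17 of 23 were higher (median 0.16, adjusted p = 0.035), among them the oxygen sensor EGLN3 at 0.27, hexokinase HK2 at 0.31, BNIP3 at 0.33 and BNIP3L at 0.25. Of 37 replication genes 27 were lower (median -0.07, adjusted p = 0.030), with the ligase LIG1 at -0.31, ORC1 at -0.29, MCM6 at -0.30 and MCM7 at -0.19. Of 29 mitotic genes 21 were lower (median -0.09, adjusted p = 0.030), with CENPF at -0.30, TTK at -0.24 and BUB1B at -0.22, and with PTTG1 at 0.21. Fry, which asks whether a list moves one way on balance and does not compare it with other genes, gave an adjusted p of 0.786 for each. Between the arrays numbered 1 the medians of the stress and hypoxia lists were 0.22 and 0.22, and between those numbered 2 they were -0.06 and 0.003; without miR-223 replicate 1 their adjusted p was 0.712, with the direction of the stress list turned, and 0.863. Without control replicate 1 these were 0.139 and 0.134, and without control replicate 2 the hypoxia list was at 0.121. Without control replicate 1, that of the mitotic list was 0.870 and that of the replication list 0.301, and without miR-223 replicate 1 these were 0.077 and 0.142. Without miR-223 replicate 2 the mitotic list was at 0.110. After quantile normalization the mitotic list was at 0.160 and the replication list at 0.071, and among genes at or above 6 the mitotic list was at 0.0501.

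**Figure D2:**
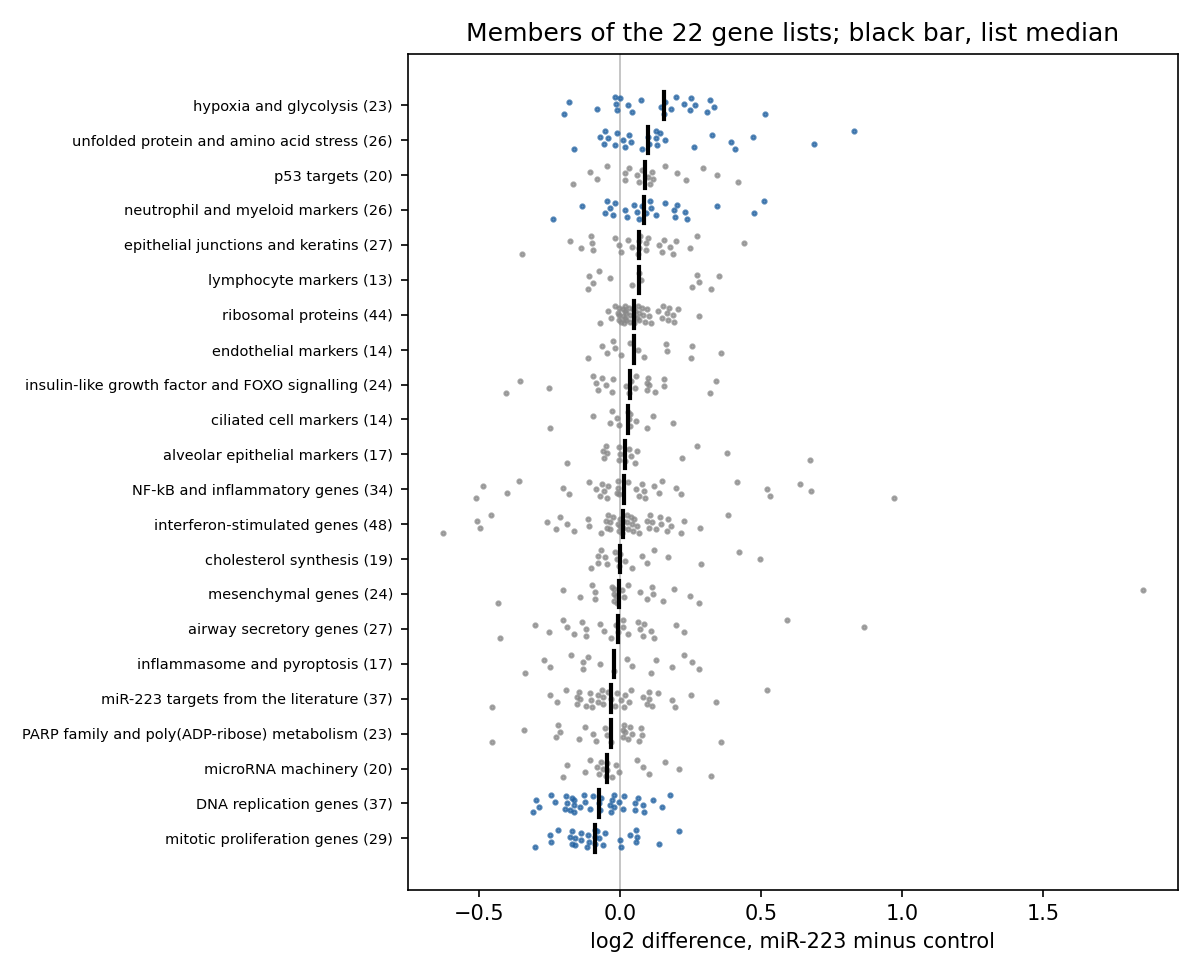
Log2 difference (miR-223 minus control, x axis) of every measured member of the 22 gene lists (rows, number of genes in brackets), with black bars at list medians. Blue lists passed camera with the preset correlation; their medians ran from -0.09 to 0.16, and none passed with an estimated correlation.

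Epithelial, secretory and mesenchymal genes did not pass as lists. In the list of junction proteins and keratins 19 of 27 genes were higher (median 0.07, camera adjusted p = 0.272; 0.025 among genes with a mean of at least 6 in either group, where the adjusted p was 0.717 with an estimated correlation, and 0.878 over all genes), with the tight junction genes CLDN1 at 0.44, CLDN3 at 0.27 and TJP3 at -0.35 and the protease ST14 at 0.25. Airway secretory genes were split 13 higher to 14 lower (median -0.01, mean 0.01, downward in camera, adjusted p = 0.853). CEACAM6, a surface adhesion protein, was 0.59 higher. It was the only gene of any list to pass when adjusted over the list alone (limma adjusted p = 0.0496, and 0.867 over all genes). The 22 lists were adjusted separately, so a pass of this kind can arise with no effect. Lysozyme, LYZ, was at 0.87 (0.44 without miR-223 replicate 2) and the mucin MUC4 at -0.30. Such single values are uncertain throughout: of the 86 list members picked by p, 49 moved by over 1.5 times or changed sign when 1 array was left out. Mesenchymal genes were split 12 to 12 (median -0.001, mean 0.08, upward in camera, adjusted p = 0.774). Their largest difference was in SNAI2, a repressor of epithelial genes, which averaged 7.10 ± 0.69 in miR-223 cells and 5.25 ± 0.82 in control cells, a difference of 1.85 ± 0.45 (SE), with an unadjusted limma p of 0.0065 that did not pass. SNAI2 was lower in the samples numbered 2 than in those numbered 1, by -0.98 in miR-223 cells and -1.16 in control cells. Between arrays of the same number its group difference was 1.76 and 1.94. FN1, fibronectin, was at -0.43, ACTA2 at 0.25 and ZEB1 at -0.20.

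Inflammatory and antiviral genes did not pass as lists. Of 34 NF-kB and inflammatory genes 17 were higher and 17 lower (median 0.01, camera adjusted p = 0.900), with the iron-binding protein LCN2 at 0.64, NFKBIZ at -0.51 and PTGS2, cyclooxygenase, at -0.40. Of 48 interferon-stimulated genes 28 were higher and 20 lower (median 0.01, adjusted p = 0.916). The median was above 0 while the mean (-0.02) and camera pointed down; IFI44L (-0.63) and IFI44 (-0.51) were low and IRF7 was at 0.22. The p53 target list had 16 of 20 genes higher (median 0.09, adjusted p = 0.073), with PHLDA3 at 0.29 and AEN at 0.34, and ribosomal protein genes had 36 of 44 higher (median 0.05, adjusted p = 0.055), with RPLP1 at 0.28. The ribosomal list passed after quantile normalization (0.012), among genes at or above 6 (0.0067) and without miR-223 replicate 1 (0.011) or control replicate 2 (0.027), and the p53 list without miR-223 replicate 1 (0.039). With an estimated correlation none of these calls held (adjusted p = 0.878 with all arrays for both lists, and 0.828, 0.717, 0.939 and 0.866 under these settings in turn). Near-identical pseudogenes make the ribosomal values uncertain. Cholesterol synthesis (median -0.0003, adjusted p = 0.655; INSIG1 at 0.50 ± 0.46 SE, STARD4 at 0.42 ± 0.43), insulin-like growth factor and FOXO signalling (median 0.03, adjusted p = 0.842; PIK3R1 at -0.35, IGFBP3 at -0.40) and the microRNA machinery (median -0.05, adjusted p = 0.774; AGO1 at -0.20) did not pass. For the cholesterol list the mean (0.07) and camera pointed up against the median (adjusted p = 0.921 with an estimated correlation). Its direction depended on which array was left out. It turned downward without miR-223 replicate 1 or control replicate 2, and stayed upward without either other array. INSIG1 and STARD4 also changed sign without miR-223 replicate 1 (-0.04 and -0.15) or control replicate 2 (-0.06 and -0.02). With 1 array left out the replicate numbers are unbalanced between the groups, and both genes were lower in the samples numbered 2 in both groups. Between the arrays numbered 1 and those numbered 2, the differences were 0.47 and 0.53 for INSIG1 and 0.55 and 0.29 for STARD4. The list medians were 0.03 and 0.03.

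Markers of other cell types were measured beside these groups. Of 26 neutrophil and myeloid markers 19 were higher in miR-223 cells (median 0.09, camera adjusted p = 0.030, and 0.878 with an estimated correlation), with neutrophil elastase, ELANE, at 0.51, CD68 at 0.48, LILRB2 at 0.35 and S100A9 at -0.24. In 1 of the 26 the mean over the arrays was at least 6 on the log2 scale, and 0 passed adjusted over the list alone. Without control replicate 1 the adjusted p of the list was 0.280, and without miR-223 replicate 1 or 2 it was 0.077 or 0.110. After quantile normalization it was 0.071. Lymphocyte markers (median 0.07, adjusted p = 0.146; GZMB at 0.32), endothelial markers (median 0.05, adjusted p = 0.272; ROBO4 at 0.36), alveolar markers (median 0.02, adjusted p = 0.368; AQP5 at 0.67, SFTPD at 0.38) and ciliated cell markers (median 0.03, adjusted p = 0.916) did not pass, although the endothelial list did without miR-223 replicate 2 (0.012; adjusted p = 0.901 with an estimated correlation, and 0.878 with all arrays).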

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

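MIR223 and RTL1 were both called under 9 of the 12 other settings for all arrays, namely the 0.10 threshold, the block, the intensity trend, robust moderation, the filter at 6, quantile normalization, median centring, probe set means and array weights. The count was 0 without moderation (MIR223 difference still 5.41), 0 with all probe sets (5.41) and 1 among genes above the median level, where RTL1 was not tested. Leaving out 1 array gave 0 to 2 genes, also at 1.5-fold, with MIR223 between 5.05 and 5.76; 1 gene remained without either miR-223 array, 2 without control replicate 1 and 0 without control replicate 2. With 1 array in a group, that array is assumed to vary like the others. The labels share replicate numbers only, and the differences between numbers 1 and 2 correlated across genes at r = 0.354 between the groups (0.676 for genes at or above 6). With the number as a replicate block the count was 3, with SNAI2 added (limma adjusted p = 0.047), and the p53 (0.048) and ribosomal (0.033) lists passed, so 7 lists did, all at 0.792 with an estimated correlation. Of the 5 called lists, stress and hypoxia passed after quantile normalization, as did the ribosomal list, which was not among the 5 (3 in all), and 0 passed with an estimated correlation (adjusted p 0.878 for the mitotic, replication, stress and hypoxia lists and for the myeloid list). Fry, which tests a list against no change and not against other genes, called 0 (0.786 for each). Quantile normalization gave 0.160 for the mitotic and 0.071 for the replication and myeloid lists, and the filter at 6 gave 0.0501 for the mitotic list. Leaving out 1 array gave 1 to 5 lists. An estimated correlation was added under the block, the filter, quantile normalization and each array left out, after these values had been seen. It gave 0 lists each time. The adjusted p ranges that follow are not from it but from camera at the preset correlation with 1 array left out. Adjusted p then ran from 0.00064 to 0.870 (mitotic), 0.024 to 0.301 (replication), 2.34e-08 to 0.712 (stress), 0.00033 to 0.863 (hypoxia), 0.027 to 0.280 (myeloid) and 0.341 to 0.989 (miR-223 targets, which turned upward without control replicate 1). Lists that had not passed changed sign in some of these settings: airway secretory (fry 0.942; arrays left out 0.712 to 0.989), mesenchymal (filter at 6, 0.716), inflammatory (filter 0.796; 0.065 to 0.278), interferon (filter 0.328, fry 0.953; 0.166 to 0.383), insulin-like growth factor (filter 0.716; 0.600 to 0.863), ciliated (quantile 0.966; 0.520 to 0.989), cholesterol (0.0063 to 0.179), endothelial (0.012 to 0.850) and microRNA machinery (0.121 to 0.906). INSIG1 ran from -0.065 to 1.06 and STARD4 from -0.15 to 0.99. With 1 array left out the replicate numbers are unbalanced between the groups, so a difference between numbers enters these values. The causes were not tested. The comparison by miR-223 sites was not run. Signal over background could not be judged without detection calls, which limits what can be said of dim genes.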

Other observations

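None of the tests below was set before all results. The tests of the imprinted region were set after the RTL1 rise had been seen, and their division by signal level after their values had. The test against level-matched lists was first written for all 5 called lists together, of which 4 lay outside, so as written it decided nothing; it was divided into 4 lists and the myeloid list after the percentiles had been seen. The other tests were written before the tested values were computed, but after related values had been seen: MIR223 on each array, the correlation of 0.354 between the number differences of the 2 groups, leading genes of the number split such as TXNIP, ARRDC4 and SCD, and its gene counts.

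Arrays that share a replicate number were alike in ways the 2 viruses do not account for. TXNIP, which inhibits thioredoxin and glucose uptake, was higher in the samples numbered 2 than in those numbered 1 by 4.11 log2 units in miR-223 cells and 3.26 in control cells, and its relative ARRDC4 by 1.18 and 1.34. The pentraxin PTX3 was higher by 1.72 and 1.37, while INSIG1, a regulator of sterol synthesis, was lower (-1.07 and -1.13), as was the desaturase SCD (-1.01 and -1.18). These genes were chosen after their values were seen, and with group and number in the limma fit 0 genes passed (adjusted p 0.121 for TXNIP), although 2559 had an unadjusted p under 0.05. Of 19 cholesterol genes 14 were lower in both groups (medians -0.31 and -0.34, camera adjusted p = 1.76e-08, but adjusted p = 0.735 with an estimated correlation), and of 34 inflammatory genes 21 were higher in both (medians 0.20 and 0.23, 1.75e-05, and 0.735).

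That structure may come from cultures in different states, for example of medium or density, or from array processing. Of 3 metabolic lists, 1, cholesterol synthesis, passed camera with medians over 0.2 in size and of the same sign in both groups, but not with an estimated correlation (adjusted p = 0.735), so a difference between cultures stays open. A shift with signal level is argued against, since the correlation between the groups was 0.368 after the trend on level was removed. Array or labelling batches that act on single genes stay open, as the labels name no batch, and every number holds both groups.

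The RTL1 rise was set against its neighbours. Of 26 other measured genes between DLK1 and DIO3, by the gene order of GRCh38.p14, 0 passed and the median log2 difference was 0.0487 (quartiles -0.05 and 0.18). Of the 26, 19 lay below the lower quartile of the tested genes on both control arrays (median control level of the 26, 2.54), where a response of the probe sets is not shown. In the other 7, DLK1 and DIO3 among them, the largest difference was 0.37 and the upper 95% limits reached 0.695, so no measured rise reached 1 log2 unit. Their control means were at most 4.69, below the median of the tested genes on each array. RMA compresses fold changes of dim probe sets, so a larger true rise of these 7 is not excluded. Activation of the region stays open, as does one limited to RTL1 and the 19 dimmest genes. Signal from the transcript made from the vector could not be decided: replicate 1 minus replicate 2 of the miR-223 arrays was 0.20 for RTL1 and -0.71 for MIR223, unlike in sign, but the RTL1 value is too small to exclude it. An effect of miR-223 or of a viral insertion on RTL1 alone also stays open and was not tested.

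The 5 list shifts may reflect genes that move together from sample to sample. The split of the arrays by replicate number called 6 lists and the crossed split 2, against 5 for the real groups. With group and number in the fit, the number difference passed camera for the mitotic and stress lists, both among these 5 (adjusted p = 0.036 for each). It also passed for the cholesterol, inflammatory, interferon and ribosomal lists. None of these calls held with an estimated correlation (adjusted p = 0.735 for each). The number, crossed and real splits called 0, 0 and 2 genes. They had 2096, 410 and 888 genes at an unadjusted limma p under 0.05, so the numbers part the arrays more widely than the viruses do. With an estimated correlation 0 lists were called under each split. In the test as divided afterwards, the medians of the stress, hypoxia, replication and mitotic lists all lay outside the central 95% of 10000 level-matched random lists. This cannot decide on a shift with signal level, since the division followed the percentiles. The random lists also drew genes singly, so lists whose members move together can lie outside. The ribosomal (percentile 100), junction and keratin (99.8) and p53 (99) lists, which were not among the 5, also lay outside. Level-matched lists had medians from -0.025 (mitotic) to 0.0009 (hypoxia), smaller in size than those of the 4 lists. For the myeloid list the percentile was 97.4, which leaves a shift with signal level open. An effect of miR-223 on these groups stays open. With 3 splits in all, no share under 0.05 can be had.

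Outside the tested genes, 921 of 14880 probe sets that are unnamed, paired with several genes or second probe sets of a gene had an unadjusted limma p under 0.05, where 744 would be expected with no effect. Their largest log2 difference was 2.56 in size, and 0 passed when all probe sets were adjusted together.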
